A study of Sus scrofa with 2 samples.

How the data were processed

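Ovaries of 6 crossbred Landrace and Yorkshire gilts were collected at 30 or 90 days after birth, and per the labels' protocols RNA of the animals of one age was combined in equal amounts into a single pool. One Illumina library was made from each pool, so each age is represented by 1 library and the spread between animals cannot be seen. How many animals entered each pool is not given in the sources used here. Each library has its own table, and its age was taken from the labels.

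Per the file headers, the authors deposited for each feature the number of uniquely assigned reads, the feature's length in bases, the percent of that length covered by reads, and an RPKM value. The deposited counts were whole numbers and summed exactly to the total in each header, 9376506 reads at 30 days and 10706106 reads at 90 days. The deposited RPKM values equalled reads per kilobase of length and scaled to that total in every row, within a relative tolerance of 1e-06, so they carry no other scaling between the libraries. The deposited coverage percent was used to describe how evenly reads lay along a feature. TopHat and Cufflinks, and genome build Sscrofa10.2, are named per the submitters' processing notes, without versions or roles. The annotation, the counting tool, the way in which the catalogue was assembled, and the library's strand and depletion chemistry are not given in the sources used here.

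The features carried identifiers of 2 kinds, Ensembl transcript identifiers and Unigene numbers. The files do not pair them with gene names, and 0 of the 88173 identifiers matched the gene name table or the RefSeq gene table of assembly Sscrofa11.1. Gene symbols, genomic positions and coding status were therefore not used here. The 25 gene lists fixed in advance (ovarian and other cell types, pathways and RNA quality) were not tested. For the same reason transcripts were not summed per gene, long non-coding RNAs were not separated from other RNAs, and features were not set beside neighbouring genes. Reads shared between near-identical features and reads of antisense pairs could not be assessed.

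A table listed only features with at least 1 read. A feature listed in one table alone was given 0 reads in the other, because the listed rows already accounted for every read of the header total. Lengths were identical for all features listed in both tables. Counts were scaled to the library total as CPM, where 1 read was worth 0.107 CPM at 30 days and 0.0934 CPM at 90 days. Features with at least 1 CPM in at least 1 library were compared by log2((CPM at 90 days + 1)/(CPM at 30 days + 1)), and a feature was called higher or lower when this reached a 2-fold difference. This pseudocount understates the change of low features. The rule is one of size: with 1 library per age no test between ages exists, and no p-value was computed. Shares of reads carry exact (Clopper-Pearson) 95% intervals, and ratios of CPM carry intervals obtained from the exact interval of the 90-day share of a feature's reads. They cover counting error in these libraries only, because reads without molecular identifiers are not independent molecules and the spread between animals is not sampled. A count of 0 was taken to allow up to 3 reads per library, a bound for 1 feature taken alone. Where a feature had no read in one library, its fold was given as a bound against that floor.

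Before the data were examined, the rule for named features took the 5 most abundant features of each library, the genes with the largest differences among those with a symbol, members of the gene lists, and the long non-coding features with the largest differences, limited to 2 per direction where no names exist. As no feature had a symbol or a coding status, the limit of 2 per direction was applied to all features, and the most abundant features are described by class and length. The pseudocount, the filter, the fold threshold and 4 scalings (median log2 ratio set to 0, upper quartile, and the TMM and median-of-ratios factors of edgeR) had alternatives fixed in advance. A total without the 4 most abundant features, RPKM in place of CPM, thinning to equal depth and 2 subsets of features were added after seeing the data.

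The ranges of Unigene numbers were also drawn after seeing the data. The boundary between the second and the third range is the split of the log2 folds along the numbers with the largest difference of means over its standard error, taken from the SD of all Unigenes. The boundary between the first and the second range is the same kind of split of the larger covered percent of each feature below it, so low coverage in the first range follows from how it was drawn. A first version, based on a running sum alone, was replaced because it favours splits near the middle of the numbers. The split was compared with 1000 shuffles of the numbers. Intervals of medians over features come from 1000 bootstrap draws of features, which are not independent replicates.

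The rule was tested on simulated counts with the real depths and feature abundances. With no change, 81 of 69304 simulated features passed 2-fold and 96.9% of the intervals held the true ratio. Of 200 features given a 2-fold change, 27 passed the rule in the right direction, since the pseudocount shrinks differences near the threshold. Of 200 given a 4-fold change 167 passed, and of 200 given an 8-fold change 198. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, matplotlib 3.10.9 for figures, and R 4.3.3 with edgeR 4.0.16 for scaling factors only.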

Results

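RNA of ovaries from gilts, young female pigs, was profiled at 30 and 90 days after birth to follow long non-coding RNA during ovary development. One library was made from a pool of animals of each age. The catalogue held 88173 features, of which 400 were Ensembl transcripts and 87773 were Unigenes, a name in common use for assembled transcript sequences. The Unigenes were between 201 and 26530 bases long, with a median of 855. The Ensembl transcripts had a median length of 135 bases, and 289 of them were shorter than 200 bases, the length below which an RNA is usually not called long. At 30 days 5674827 reads were assigned to Ensembl transcripts and 3701679 to Unigenes, and at 90 days 7725176 and 2980930. The median listed feature had 20 reads at 30 days and 18 at 90 days. The files do not pair the identifiers with gene names. No library was replicated, so the differences describe these pools and have no replicate check.

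A small number of abundant RNAs held most of the reads of both pools. The 4 most abundant features, all Ensembl transcripts, took 55.7% of the reads at 30 days and 69.3% at 90 days. The transcript of 1571 bases was the most abundant in each pool, with 27.2% of the reads at 30 days and 35.7% at 90 days, a ratio of 1.312 (95% interval 1.310 to 1.314). The transcript of 960 bases had 3.22% of the reads at 30 days and 11.1% at 90 days, a ratio of 3.43 (3.42 to 3.45). The transcript of 328 bases had 5.54% and 8.49%, a ratio of 1.53 (1.527 to 1.537). In the opposite direction, the transcript of 331 bases had 19.7% and 14.1%, a ratio of 0.714 (0.712 to 0.715). The transcript of 258 bases had 2.07% and 1.19%, a ratio of 0.576 (0.571 to 0.580). The Unigene of 4993 bases, the only Unigene among the 5 most abundant features of either pool, held 1.79% of the reads at 30 days and 2.17% at 90 days, a ratio of 1.21 (1.207 to 1.222). With the library total as the scale, the 960-base transcript alone among these features passed the 2-fold rule. The intervals cover counting error only. Relative to the reads outside the 4 most abundant features, the ratio of the 331-base transcript was 1.03 and that of the 258-base transcript 0.831, so the direction of the former depended on the scaling. On that scale the ratio of the 328-base transcript was 2.21, and it also passed 2-fold with upper-quartile rescaling and with TMM and median-of-ratios factors.

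**Figure D1:**
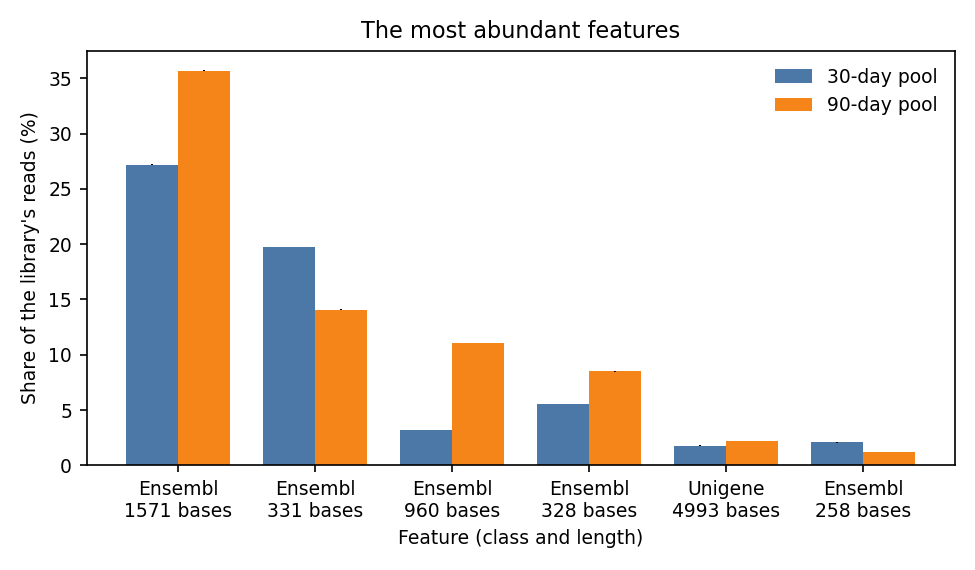
Share of each library's reads, in percent, taken by the features among the 5 most abundant of either pool, named by class and length. Blue bars are the 30-day pool and orange bars the 90-day pool, with exact 95% intervals of counting error that are too small to see; the 960-base transcript has 3.22% of the reads at 30 days and 11.1% at 90 days.

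As classes, the Ensembl transcripts held 60.5% of the reads at 30 days and 72.2% at 90 days, and the Unigenes held the remaining 39.5% and 27.8%. Outside the 4 most abundant features, 4155947 reads were left at 30 days and 3284667 at 90 days. A total without these features raised every log2 ratio (90 days over 30 days) by 0.53. Every CPM rose with it, while the pseudocount and the 1 CPM filter stayed fixed. Folds with the pseudocount, and counts, made with this total therefore differ by more than scaling. Over the 36142 features with at least 1 CPM in both pools, the median log2 ratio was -0.19 with the total of all reads and 0.34 with the total without the 4 most abundant features. The median was 0.20 with TMM factors, 0.22 with median-of-ratios factors and 0.28 with upper-quartile rescaling.

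More features were detected in the 30-day pool, which also had more reads outside the 4 most abundant features. At least 1 CPM was found for 60367 features at 30 days and 49748 at 90 days, and 36142 features reached it in both. Any read at all was found for 83244 features at 30 days and 78175 at 90 days, with 73246 shared. The 9998 features with reads only in the 30-day pool had a median of 16 reads there, and 8794 of them were Unigenes numbered 12191 to 73609. Of all 9998, 3838 had at least 20 reads and were at least 7.61-fold lower at 90 days, against the 3 reads that a count of 0 allows. The 4929 features with reads only in the 90-day pool had a median of 4 reads, and 3972 of them were Unigenes numbered 73610 to 127855. Of all 4929, 805 had at least 20 reads and were at least 5.84-fold higher at 90 days against the same floor. These bounds use the library total and hold for 1 feature taken alone, not for all of these features together.

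The comparison of the ages covered 73973 features with at least 1 CPM in at least 1 pool. Of these, 10810 were at least 2-fold higher at 90 days, 27103 were at least 2-fold lower, and 36060 lay between. Counting error alone, simulated without any difference and with the catalogue taken as fixed, put 81 features past the rule. The simulation covers neither the spread between animals nor how features entered the catalogue. The exact 95% interval lay wholly beyond 2-fold for 6514 of the higher and 21631 of the lower features. At a 4-fold difference 1101 features were higher and 6700 lower, and at 16-fold 18 were higher and 113 lower. Lower features made up 71.5% of those past 2-fold, and this split moved with the scaling. It was 64.8% with the median log2 ratio set to 0, 58.5% with TMM factors and 57.5% with median-of-ratios factors. Upper-quartile rescaling gave 55.0%, and the total without the 4 most abundant features 51.7%. That total also compared more features, 80995, since every CPM rose against a fixed pseudocount and filter.

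The features named here have the 2 largest and the 2 smallest values of log2((CPM at 90 days + 1)/(CPM at 30 days + 1)), an order that the pseudocount sets in part. Unigene103826_All (7878 bases) had 18 reads at 30 days and 1265 at 90 days, a 61.5-fold higher CPM at 90 days (38.8 to 104.2). Unigene109171_All (2555 bases) had 6 and 688 reads, a 100.4-fold higher CPM (45.9 to 274.6). The part of their length covered by reads was 11.6% at 30 days and 95.2% at 90 days for the former, and 9.90% and 99.9% for the latter. In the opposite direction, Unigene39043_All (6097 bases) had 2149 reads at 30 days and 31 at 90 days, a 79.2-fold higher CPM at 30 days (55.6 to 116.8). ENSSSCT00000020970, an Ensembl transcript of 113 bases, had 490 reads at 30 days and none at 90 days. It was at least 186-fold lower at 90 days against a floor of 3 reads. This bound takes the 490 reads as exact and holds for 1 feature taken alone, not for one picked as an extreme. The exact interval of its CPM ratio (90 days over 30 days) reached up to 0.00662, a weaker bound. In plain CPM ratios the order differs: a feature with no read at 30 days and 374 at 90 days was at least 109-fold higher.

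**Figure D2:**
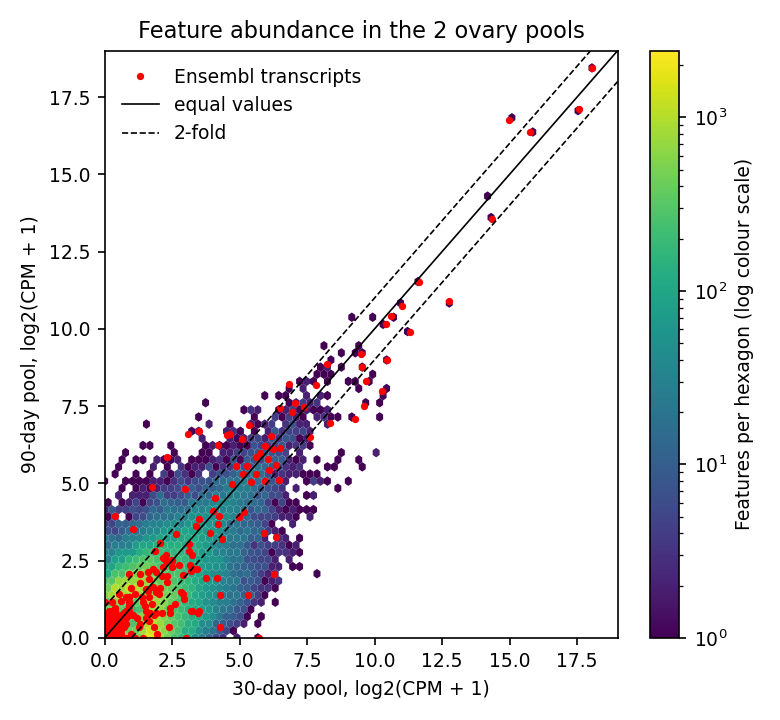
Abundance of each feature in the 30-day pool (horizontal) and the 90-day pool (vertical), as log2(CPM + 1). Colour gives the number of features per hexagon on a log scale, red points are the Ensembl transcripts, the solid line marks equal values and the dashed lines a 2-fold difference; 27103 tested features lie on or past the lower dashed line and 10810 on or past the upper one, a split that moves with the scaling.

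Among the Ensembl transcripts, 156 reached 1 CPM in at least 1 pool. Of these, 17 were at least 2-fold higher and 45 at least 2-fold lower at 90 days, with a median log2 fold of -0.31. Those under 200 bases gave 11 higher and 33 lower of 106, and those of at least 200 bases 6 higher and 12 lower of 50. The direction did not hold under every scaling. TMM factors gave 26 higher and 34 lower of 156, and upper-quartile rescaling 27 and 32 of 165. The total without the 4 most abundant features gave 50 and 43 of 204, with a weaker pseudocount and filter. The median log2 fold with these scalings was 0.07, 0.20 and 0.31. Among the 519 features of both classes with a mean of at least 50 CPM, 43 were higher and 153 lower with the library total. Lower features outnumbered higher ones with the 4 scalings fixed in advance. The counts ranged from 61 higher and 127 lower (median log2 ratio set to 0) to 92 and 107 (upper-quartile rescaling). The total without the 4 most abundant features gave 104 higher and 103 lower.

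Among the Unigenes, 10793 were higher and 27058 lower of 73817, and taken over all abundances the direction followed the Unigene number. The log2 fold changed abruptly after number 73609. In the range from 12191 to 73609, called the second range, 25251 of 39589 compared features were at least 2-fold lower at 90 days and 399 were higher, with a median log2 fold of -1.27. In the range from 73610 to 127855, called the third range, 10374 of 33764 were higher and 1745 lower, with a median of 0.67. The features numbered 1940 to 12173, the first range, gave 20 higher and 62 lower of 464, and 264 higher and 143 lower of 1078 with the total without the 4 most abundant features. Over all compared features, the opposite directions of the second and the third range held under each scaling run. Lower features made up at least 95.3% of those past 2-fold in the second range and at most 14.4% in the third. With the library total, however, lower features outnumbered higher ones in the third range too from a mean of 10 CPM upwards, although most features lay between. The third range gave 211 higher and 406 lower of 1499 at 10 to 20 CPM and 75 and 280 of 855 at 20 to 50 CPM. At 50 CPM and over it gave 16 and 99 of 303. In the second range lower features also outnumbered higher ones at these abundances. The counts were 111 higher and 771 lower of 1419 at 10 to 20 CPM and 56 and 264 of 598 at 20 to 50 CPM. At 50 CPM and over they were 19 and 42 of 170. Unigene39043_All lies in the second range, and Unigene103826_All and Unigene109171_All lie in the third.

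Coverage also differed between the ranges, in part by how they were drawn. Covered length follows read number, and the boundary after 73609 was placed by the folds. The median read number was 25 at 30 days and 6 at 90 days in the second range, and 10 and 24 in the third. The 45683 features of the second range had a median of 89.1% of their length covered at 30 days and 33.0% at 90 days. The 40004 features of the third range had 52.3% at 30 days and 87.9% at 90 days. In the first range, of 2086 features, the medians were 5.51% and 4.45%, low values that follow from how this range was drawn.

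**Figure D3:**
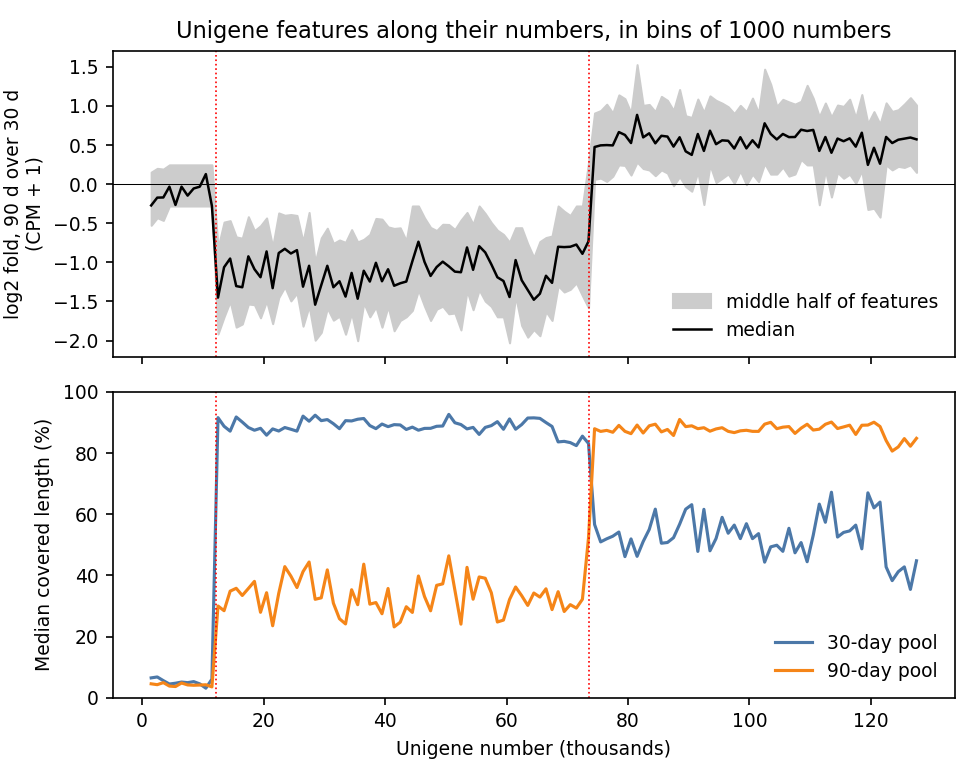
Unigene features in bins of 1000 numbers along the horizontal axis, with the median (line) and interquartile range (grey) of the log2 fold of CPM + 1, 90 days over 30 days, in the upper panel, and the median covered length in percent in the 30-day (blue) and 90-day (orange) pool in the lower panel. Dotted red lines mark the ends of the first and the second range; the median log2 fold over a whole range, with untested features included, is -1.12 in the second and 0.56 in the third.

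From a mean of 1 CPM upwards, the difference between the second and the third range narrowed with abundance. At 0.5 to 1 CPM the gap of the median log2 folds was 1.85 (95% bootstrap interval over features 1.83 to 1.92). At a mean of 1 to 2 CPM, the median log2 fold was -1.31 in the second range and 0.77 in the third, a gap of 2.07 (2.06 to 2.10). At 5 to 10 CPM the gap was 1.58 (1.51 to 1.65) and at 10 to 20 CPM 0.97 (0.83 to 1.11). At 20 to 50 CPM it was 0.25 (0.11 to 0.45). At 50 CPM and over the medians were -0.13 in 170 features of the second range and -0.49 in 303 features of the third, a gap of -0.35 (-0.57 to -0.11). Features are not independent replicates, and these intervals describe the 2 libraries.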

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

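All tests in this part were chosen after the split along the numbers was seen. The 5-point bound for covered length at equal read numbers was set before that value was computed, but after the plain medians of covered length and the narrowing gap were known.

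The covered length was not used in the comparison of ages, but it set the end of the first range. Its plain medians differed between the later ranges of Unigene numbers, as read numbers did. In the range from 12191 to 73609 the median feature was covered over 89.12% of its length at 30 days and 32.99% at 90 days, and in the range from 73610 to 127855 over 52.31% and 87.86%.

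The tables argue against numbers without order, since the split at 73609 had a statistic of 202.07 (difference of means over its standard error) and at most 4.55 in 1000 shuffles, and against an age difference shared by the features of a range at every abundance, since the gap of medians was 2.07 at 1 to 2 CPM but -0.35 (-0.57 to -0.11) at 50 CPM and over. A candidate explanation is that the second range was assembled from the 30-day reads and the third from the 90-day reads. A low feature would then have had to be well covered in 1 library to enter the catalogue. This predicts a gap that shrinks at high abundance, but not the reversed gap of -0.35, which stays unexplained. A further comparison took features with 10 to 50 reads at 30 days and nearly equal numbers in both libraries. The median difference in covered percent (30 days minus 90 days) was 9.21 (8.58 to 10.01) in 2129 features of the second range. It was -5.22 (-5.70 to -4.61) in 2679 of the third and 0.28 (-0.16 to 0.91) in 75 of the first. The latter had medians of 8.92% covered at 30 days and 8.93% at 90 days. In a range drawn for low coverage this leaves little room for such differences, so its value is no control for the other ranges. The second and the third range were thus covered more broadly in their presumed source library, by 9.21 and 5.22 points, but the interval of the third range reaches below the bound of 5 set for this test, and this comparison took the place of one of plain medians, which follow read number. On this hypothesis the counts of Unigenes seen in one pool only in large part record the library a feature was assembled from. The same would hold for the counts of higher and lower Unigenes near the floor. The gap between the ranges was not confined to the floor, however. It was 1.58 at 5 to 10 CPM and 0.97 at 10 to 20 CPM, and whether the hypothesis accounts for these gaps was not tested. Age differences of single features stay open and were not tested either.

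Of features with at least 20 reads, 393 at 30 days and 464 at 90 days had under 30% of their length covered, although random placement of reads of 90 bases would cover at least 60%, and 147 of them did so in both libraries.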

How the results depend on the processing

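The total without the 4 most abundant features, RPKM, thinning and both subsets were chosen after seeing the data. No paired analysis was possible because each age has 1 library, which also rules out leaving a library out. Sums per gene, gene lists, the long non-coding class and neighbouring genes were not run for want of names and positions. Of the counts and shares under an alternative, 15 stayed within 1.5 times the count or within the interval of the share and 33 moved. The 3 values without a filter equal the main ones by construction, as a feature under 1 CPM in both libraries cannot reach 2-fold with a pseudocount of 1.

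Against 10810 higher and 71.5% lower among the changed, a pseudocount of 0.1 gave 17434 and 65.5%, and 0.01 gave 18081 and 65.0%, because a smaller pseudocount shrinks the folds of low features less. A minimum of 5 CPM gave 2839 higher, 9152 lower and 76.3% with fewer features tested, and a 4-fold threshold 1101, 6700 and 85.9%. The lower share was 64.8% with the median log2 ratio set to 0, 58.5% with TMM factors, 57.5% with median-of-ratios factors and 69.5% with RPKM. Upper-quartile rescaling gave 18457 higher and 55.0%, the total without the 4 most abundant features 24739 and 51.7%, and thinning the reads outside them to 3284667 in each library 24591 and 51.8%. Scaling factors shift each ratio by construction. The total without the 4 most abundant features also raised every CPM against a fixed pseudocount and filter, so its counts do not show scaling alone. Thinning shares this limit, as it compared 81308 features against 73973 with the library total, and is not a separate check. Outside the second and the third range 37 were higher and 107 lower (74.3%) of 620, and at a mean of at least 50 CPM 43 and 153 (78.1%) of 519, with fewer features tested. The first of these directions depends on the scaling. With the total without the 4 most abundant features 314 were higher and 186 lower (37.2%) of 1282 outside these ranges. The lower share there was 41.8% with upper-quartile rescaling and 49.6% with median-of-ratios factors. It was 51.4% with TMM factors and 61.2% with the median log2 ratio set to 0. At a mean of at least 50 CPM it was 49.8% (104 higher and 103 lower) with the total without the 4 most abundant features. With the other 4 scalings, in the same order, it was 53.8%, 55.4%, 58.5% and 67.6%, so each kept a lower majority.

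Features detected at 5 CPM were 15824 at 30 days, 9816 at 90 days and 6100 in both. At 90 days 78175 were detected above 0 and 75736 at 0.1 CPM, and in both pools 73246 and 71189. At 0.1 CPM 1 read suffices at 30 days and not at 90 days, so depth limits this comparison.

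Of the log2 folds of the named and most abundant features under an alternative, 32 stayed within the counting interval of the main value, 45 moved beyond it and 1 reversed. A further 2 could not move, since rescaling the 90-day library alone leaves a count of 0 there at 0. The 331-base transcript had -0.49 with the library total and 0.045 with the total without the 4 most abundant features. Its share fell less than that of the reads outside these 4.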

Other observations

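All tests in this part were chosen after the results were seen.

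The abundant features were not alike in their change. Per base, the 960-base transcript had 0.194 times the reads of the 1571-base transcript at 30 days and 0.508 times at 90 days. Together both held 30.4% of the reads at 30 days and 46.7% at 90 days. A hypothesis for their identity is that 2 of the 4 most abundant features are the mitochondrial rRNAs. The RefSeq gene table of assembly Sscrofa11.1 lists 2 mitochondrial rRNA genes, and their lengths are exactly 960 and 1571 bases. Each length occurs once among the 400 Ensembl transcripts, of which 25 have at least 500 bases. The match rests on length alone, and 81 Unigenes also have one of these lengths. Whether library preparation or RNA turnover changed the ratio of this pair was not tested.

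The larger share of the 4 most abundant features was weighed as the cause of the lower median ratio at 90 days. With a total without them the median log2 ratio was 0.34 in place of -0.19, but this adds the same 0.53 to every ratio, so the change of sign is arithmetic and the explanation stays open, as does an age difference of the median feature, which was not tested. Of the 36142 features, 49.4% had more reads at 30 days, 49.1% had more at 90 days and 1.47% had equal numbers, so the median lies at equal read numbers and its sign is set by the total chosen. The mix of number ranges also enters this median, which was -0.98 in the second range and 0.43 in the third. Which scaling places unchanged features at 0 cannot be decided from 1 library per age.

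Features with neighbouring numbers had similar folds within a range. Across features, which are not independent replicates, the correlation with the next listed number was r = 0.433 (Spearman's rho 0.440) in the second range and 0.486 (0.396) in the third, with an absolute r of at most 0.0169 in 1000 shuffles, which argues against independent neighbours. The correlation was 0.253 and 0.292 at a distance of 10 listed numbers, and at most 0.00557 in size at 200. Neighbouring numbers may hold parts of the same or of adjacent transcripts, but co-regulated neighbouring loci predict the same decline, and without coordinates these cannot be told apart. In both cases counts of features overstate the number of independent differences.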
